A study of Rattus norvegicus with 6 samples.

How the data were processed

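RNA was taken from cultures described as primary neonatal rat ventricular cells, infected with Ad-GFP or Ad-Otud1 and treated with 10 µM angiotensin II for 24 h, and libraries were made with a kit for messenger RNA, per the labels' protocols. The authors deposited whole-number read counts per gene, not normalised, as a table of 6 libraries and again library by library, and the library columns of the table were identical to the separate files. Per the submitters' processing notes, the tools were HISAT2 2.2.1, an aligner, and featureCounts 1.6.1, a read counter, with genome build Rnor_6.0. The gene annotation release, the strand setting, the treatment of reads that match several places and any filter on genes were not given in the sources used here. The table held 18482 genes with Ensembl identifiers, names and positions, each with at least 1 count in total. Strandedness being unstated, overlapping and antisense genes may share reads, and genes with near-identical copies are uncertain. For 259 genes the name was missing or shared with another gene, and these are identified by their Ensembl identifier.

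Library totals were 15540832 to 17678440 counts, so 1 CPM corresponds to about 15.5 to 17.7 counts, and a count of 0 in the smallest library allows up to 0.194 CPM (3 counts). Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The 20 largest genes took 10.4% ± 0.316 of counts in Ad-GFP and 10.4% ± 0.0804 in Ad-Otud1. Libraries of a group differed by more than sampling noise, with a median chi-square over its sampling expectation of 2.83 in Ad-GFP and 2.03 in Ad-Otud1 and no pair below 1.94, so all 6 were kept as separate samples. The labels name no sequencing batch.

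Samples were grouped by their titles. Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F-test, two-sided), comparing 3 Ad-Otud1 with 3 Ad-GFP libraries with no other term. The filter left 12552 genes and removed 5930. TMM factors ran from 0.994 to 1.01, and the common biological coefficient of variation was 7.01%. The p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, and every adjusted p of a gene comes from this edgeR test unless another tool is named. Levels are CPM computed from the deposited counts with the TMM factors, as mean ± SD, and fold changes are edgeR's. Standard errors were derived from the fold change and the F statistic.

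Before the data were examined, 34 gene lists were fixed, covering hypertrophy, sarcomere, calcium handling, renin-angiotensin, matrix, NF-κB, interferon, ASK1 and MAPK components, immediate-early genes, p53, cell death, endoplasmic reticulum stress, NRF2, oxidant sources, oxidative phosphorylation, mitochondrial dynamics, fatty acid oxidation, glycolysis, cholesterol, cell cycle, hypoxia, OTU deubiquitinases, proteasome, chaperones, atrophy and autophagy, ribosome and markers of 8 cell types. Of 633 distinct list genes, 574 were matched by their name in the table, 11 through a synonym in the RefSeq gene table of assembly GRCr8, used for names only, and 48 were not matched and not analysed here. The table holds only genes with at least 1 count, so an unmatched gene may have another name or may have had no reads. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), with the p adjusted over the 31 lists so tested. Camera asks whether the members stand apart from the other genes.

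The genes to be named were also fixed before the data were examined. They were Otud1, Pgam5 and Map3k5; the 10 genes with the largest rise and the 10 with the largest fall among those with a proper symbol, a mean log2 CPM of at least 1, an adjusted p below 0.05 and no overlap between the groups; up to 4 members of each list with the smallest adjusted p; and Nppa, Nppb, Myh7, Myh6 and Acta1. Other genes named are list members near the floor, given as levels, and genes said to be chosen after their values were seen.

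The code was tested on simulated counts drawn from the real means, library sizes and dispersions of this comparison, for 12552 genes of which 200 were changed. It recovered 28% of genes changed 1.2-fold, 72% at 1.5-fold, 84% at 2-fold and 94% at 4-fold. Of 160 calls, 21 were unchanged genes, and 15 of the 21 had a simulated coefficient of variation above 20%. The false share was thus 13.1%, above the 5% aimed at, in a simulation with far fewer changed genes than were called in the real data. A robust dispersion estimate left 15 unchanged genes among 154 calls. No unchanged list was called, but the simulated genes varied independently of each other. The simulation therefore did not test lists whose members move together.

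Alternatives fixed before the data were examined were median-of-ratios, upper-quartile and no composition scaling, no filter, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, Otud1 left out of the counts, and for lists an estimated correlation and fry. Added after the data were seen were a test against a 1.5-fold change (glmTreat), the robust dispersion estimate, leaving out genes whose CPM differed over 2-fold between libraries of a group, and 6 further gene lists, of which 5 are given. These lists were chosen for patterns already seen, so their members are only counted and no list test is given for them. Some genes and 1 of these lists are not reported here.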

Results

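The data were RNA-seq read counts per gene from cultures described in their record as primary neonatal rat ventricular heart cells, enriched for cardiomyocytes by letting the faster-adhering cells settle out. Several heart structural genes were near the floor in all libraries, with the levels given below. All cultures were stimulated with 10 µM angiotensin II, a peptide hormone that drives hypertrophic growth of heart muscle cells, for 24 h. Before that they had been infected with an adenovirus carrying either green fluorescent protein (Ad-GFP, the control) or Otud1 (Ad-Otud1), which encodes a deubiquitinase of the ovarian tumour (OTU) family. Each group held 3 libraries. Library totals ran from 15540832 to 17678440 counts in Ad-GFP and from 15542494 to 16083878 in Ad-Otud1, over 18482 genes. The title of the series places Otud1 upstream of the mitochondrial phosphatase Pgam5 and the kinase ASK1 (gene Map3k5) in pathological hypertrophy, so the question put to the data was which transcripts differed when Otud1 was overexpressed under angiotensin II. There was no group without angiotensin II, and therefore no measurement of the response to the hormone itself.

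Otud1 itself was higher in Ad-Otud1, at a library-size-normalised count (CPM) of 27.8 ± 1.89 (SD, n = 3) against 16.9 ± 2.15 in Ad-GFP, a 1.64-fold difference. The 3 Ad-GFP libraries held 271, 321 and 251 Otud1 counts and the 3 Ad-Otud1 libraries 431, 413 and 471, so the groups did not overlap. The log2 fold change was 0.72 ± 0.10 (SE), with an adjusted p of 6.96e-05 in edgeR's quasi-likelihood test. Among the 3045 genes that were higher in Ad-Otud1, Otud1 ranked 587 by fold change. The counted gene model spans 1368 bp, from 86408151 to 86409518 on chromosome 17 of Rnor_6.0. An exact two-sided permutation test on the CPM gave p = 0.1, the smallest value that 3 against 3 libraries allow. Against a minimum change of 1.5-fold, an added test gave an adjusted p of 0.316 in edgeR.

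The transcripts of Pgam5 and Map3k5, the other genes of the series title, moved in opposite directions and by small amounts. Read counts do not measure the amount, ubiquitination or activity of the proteins, so they do not test the order of action in the title. Pgam5 rose 1.27-fold, from 85.9 ± 4.15 to 109 ± 0.813 CPM (log2 fold change 0.35 ± 0.04, adjusted p = 4.40e-05). Map3k5 fell 1.35-fold, from 16.2 ± 1.39 to 12 ± 2.0 CPM (log2 fold change -0.43 ± 0.13, adjusted p = 0.0157). The Map3k5 call was lost when some single libraries were left out, with an adjusted p of 0.0596 without Ad-GFP replicate 2 and 0.0544 without Ad-Otud1 replicate 3. In Rnor_6.0, Pgam5 lies on chromosome 12 from 52467450 to 52474511 and Map3k5 on chromosome 1 from 15412603 to 15613746.

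Most tested genes of the hypertrophic and fetal heart programme list rose in Ad-Otud1. Nppa, encoding atrial natriuretic peptide, rose 3.33-fold from 12.4 ± 0.933 to 41.4 ± 1.50 CPM. Nppb, encoding brain natriuretic peptide, rose 3.43-fold from 8.23 ± 0.915 to 28.2 ± 0.748 CPM. Acta1, the skeletal alpha-actin that fetal hearts express, rose 3.31-fold to 46.5 ± 2.73 CPM, and the slow myosin heavy chain Myh7 rose 2.44-fold to 8.35 ± 0.371 CPM. Rcan1, a target of calcineurin signalling, rose 2.24-fold and the matricellular factor Ccn2 rose 1.86-fold. The adult fast myosin heavy chain Myh6 also rose, 10.6-fold from 2.10 ± 0.167 to 22.3 ± 1.43 CPM. Of the 14 tested members of the hypertrophy list, 10 rose and none fell, and the counts were the same when adjusted over the list alone. The 4 that did not pass included Ankrd1, named here after its values were seen. It stood at 1245 ± 8.13 CPM in Ad-GFP and 1240 ± 17.7 CPM in Ad-Otud1 (adjusted p = 0.846 in edgeR). The list stood above the other genes in camera (adjusted p = 1.93e-09, and adjusted p = 0.0288 with an estimated correlation), with a median log2 fold change of 1.03. The libraries that carried these higher levels also carried more cardiomyocyte, fibroblast and mural marker transcripts, given with their values below. They also carried more transcripts of a skeletal muscle list chosen after the data were seen, in which 12 of 18 tested members rose and 1 fell. Myog, a regulator of skeletal muscle differentiation, rose 2.47-fold from 73.1 ± 1.56 to 181 ± 5.78 CPM, and the embryonic myosin Myh3 rose 4.10-fold.

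**Figure D1:**
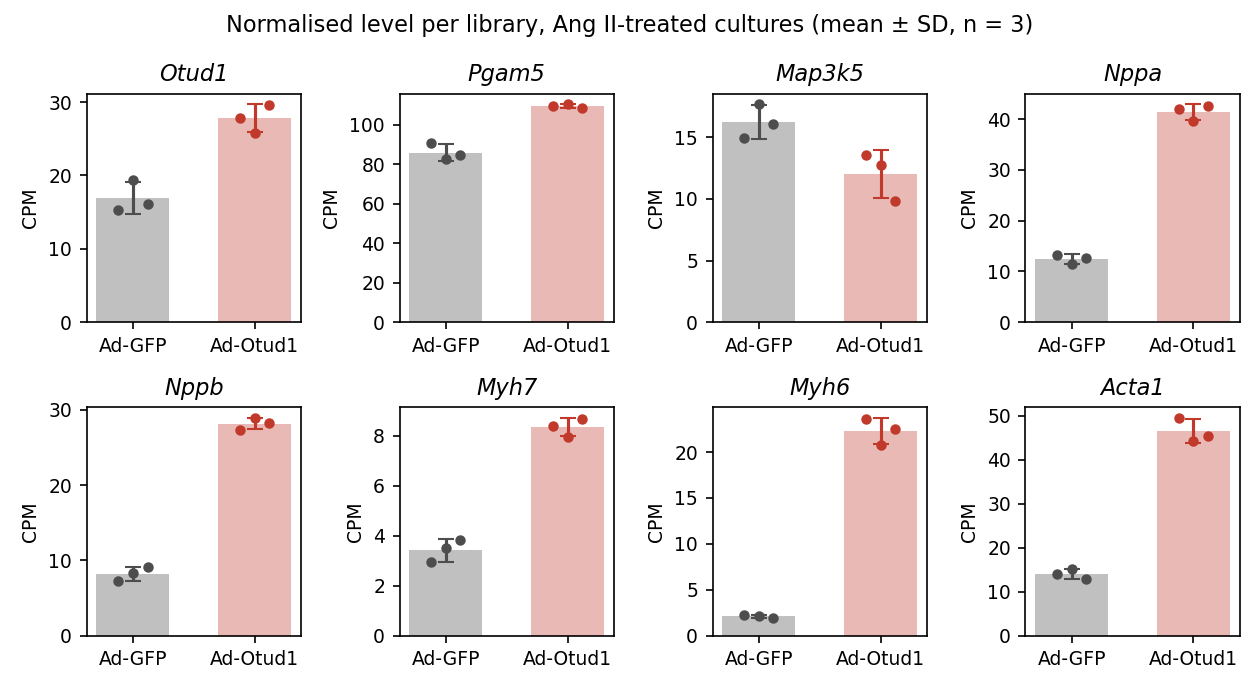
Normalised level in CPM on the vertical axes for 8 genes, with each point a library, each bar the group mean and each error bar the SD (n = 3; grey, Ad-GFP; red, Ad-Otud1; all with angiotensin II). Otud1 stood at 27.8 against 16.9 CPM, and Map3k5 was the gene of the 8 that was lower in Ad-Otud1.

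Of the tested cardiomyocyte markers most rose, whereas calcium handling and ion channel genes went both ways. Pln, encoding the calcium pump inhibitor phospholamban, rose 8.33-fold from 14.8 ± 1.03 to 123 ± 2.97 CPM. The ryanodine receptor Ryr2 rose 7.90-fold from a low level of 0.437 ± 0.102 to 3.53 ± 0.252 CPM, and the troponin Tnnt2 rose 1.57-fold from 259 ± 1.56 to 406 ± 7.49 CPM. Of 6 tested cardiomyocyte markers, 4 rose and none fell, also when adjusted over the list alone (camera adjusted p = 1.93e-09, and adjusted p = 0.0238 with an estimated correlation). In the calcium and ion channel list, 7 of 15 tested members rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.24e-05, and adjusted p = 0.0293 with an estimated correlation). The calcium pump Atp2a2 rose 3.43-fold, the kinase Camk2d rose 3.75-fold, and the gap junction gene Gja1 fell by 0.66 on the log2 scale. In the sarcomere list, 9 of 16 tested members rose and 2 fell, or 10 and 2 adjusted over the list alone. Csrp3, a Z-disc protein, rose 6.92-fold and Ldb3 rose 1.58-fold. The sarcomere list passed camera at an adjusted p of 0.00860, a call lost at adjusted p = 0.191 with an estimated correlation. Most tested members of the skeletal muscle list were higher in the same libraries.

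Several structural heart genes were close to the detection floor in both groups, so those lists rest on the remaining members. Actc1, the cardiac alpha-actin, held 16 counts summed over the Ad-GFP libraries and 30 over the Ad-Otud1 libraries. Actn2 held 11 and 28 summed counts, Tnni3 14 and 10, and Mybpc3 30 and 38. Of the 11 cardiomyocyte markers in the table, 5 reached 1 CPM in every library. Markers of fibroblasts and mural cells were measured in the same libraries. Among fibroblast markers, 6 of 8 tested members rose and none fell, with the same counts adjusted over the list alone (camera adjusted p = 1.14e-09, and adjusted p = 0.0238 with an estimated correlation). The actin-severing protein Gsn rose 11.9-fold from 24.6 ± 1.11 to 293 ± 4.49 CPM and the collagen receptor Ddr2 rose 1.98-fold. Other fibroblast markers were near the floor, with Pdgfra at 5 and 6 summed counts, Dpt at 5 and 0 and Dcn at 33 and 41. Of the 10 fibroblast markers in the table, 7 reached 1 CPM in every library. Among mural markers, 6 of 11 tested members rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.19e-06, and adjusted p = 0.0288 with an estimated correlation). The smooth muscle actin Acta2 rose 4.15-fold from 782 ± 52.9 to 3249 ± 67.5 CPM, and Pdgfrb rose 1.50-fold. Ptprc, a general leukocyte gene, held 2 and 1 summed counts. The leukocyte list did not pass camera (adjusted p = 0.689), with none of its 5 tested members higher and 1 lower, also adjusted over the list alone. That member was Csf1r, the receptor for macrophage colony-stimulating factor, which fell by 3.24 on the log2 scale, from 2.87 ± 0.0393 to 0.296 ± 0.159 CPM. The epicardial and mesothelial list did not pass either (adjusted p = 0.895; of 5 tested members, 1 higher and 2 lower, also adjusted over the list alone). Endothelial and Schwann or neuronal markers had 3 tested members each and erythroid markers 0, too few for camera. Of these, the endothelial receptor Flt1 rose 1.14-fold, and the Schwann-cell receptor Erbb3 rose 2.29-fold together with Tubb3, which made 1 of 3 and 2 of 3 tested members.

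**Figure D2:**
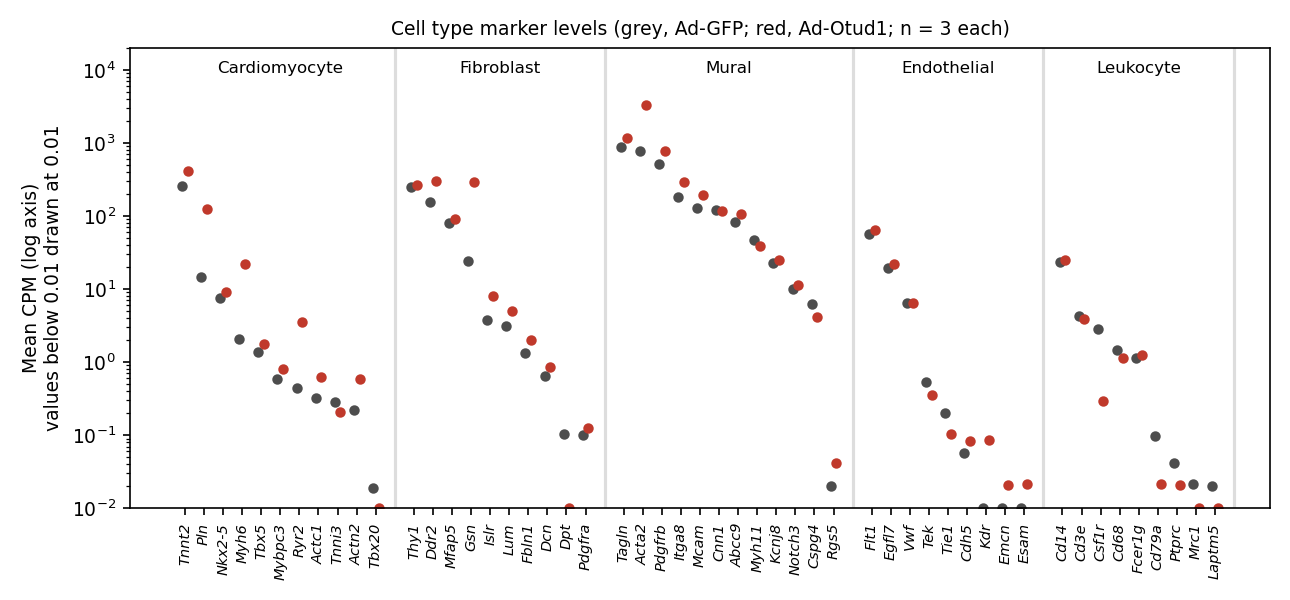
Mean CPM (log axis, n = 3 per group) of marker genes of 5 cell types that a ventricular culture could hold, in Ad-GFP (grey) and Ad-Otud1 (red). Tnnt2 stood at 259 and 406 CPM and Acta2 at 782 and 3249 CPM, whereas Actc1, Actn2, Tnni3, Pdgfra and Ptprc lay below 1 CPM in every library.

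Cell cycle genes fell without exception among the tested list members. All 27 fell, by a median of 2.86-fold (median log2 fold change -1.52), and all 27 fell when adjusted over the list alone. Mcm6 and Mcm5, subunits of the replicative helicase, fell 4.37-fold and 4.25-fold, Mcm6 from 216 ± 3.40 to 49.4 ± 1.6 CPM. Rrm2, a subunit of ribonucleotide reductase, fell 3.80-fold. Top2a, the DNA topoisomerase of dividing cells, fell 2.74-fold from 383 ± 8.30 to 140 ± 3.18 CPM. The list had the smallest p of the 31 tested in camera (adjusted p = 6.90e-92, and adjusted p = 0.000690 with an estimated correlation).

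Genes of cholesterol synthesis fell almost as uniformly. Of 20 tested members, 19 fell and none rose, also when adjusted over the list alone, with a median fall of 2.37-fold. Hmgcs1, an early enzyme of the mevalonate pathway, fell 2.80-fold from 421 ± 15.7 to 151 ± 0.699 CPM. Sqle, the squalene epoxidase, fell 2.68-fold and the demethylase Cyp51 fell 2.11-fold. Dhcr7, which makes cholesterol from 7-dehydrocholesterol, was among the 10 named genes with the largest falls, at 4.65-fold. The list passed camera at an adjusted p of 1.32e-53, and at adjusted p = 0.00133 with an estimated correlation.

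Most tested genes of the NF-κB list were higher in Ad-Otud1, whereas the list for endoplasmic reticulum stress held members moving both ways. In the NF-κB list, 17 of 21 tested members rose and none fell, or 18 and none adjusted over the list alone. The chemokine genes Cxcl1, Ccl2 and Ccl7 rose 2.66-fold, 2.70-fold and 2.02-fold, and the adhesion molecule Icam1 rose 1.90-fold to 219 ± 3.71 CPM. Camera gave an adjusted p of 1.12e-07, and adjusted p = 0.0293 with an estimated correlation. In the list for endoplasmic reticulum stress and the integrated stress response, 11 of 20 tested members rose and 6 fell, also adjusted over the list alone. Members that rose included Asns, the asparagine synthetase, at 2.75-fold, the pseudokinase Trib3 at 2.50-fold, Ppp1r15a, a regulatory subunit of the phosphatase acting on eIF2α, at 2.32-fold and the transcription factor Atf5 at 2.10-fold. Members that fell included Creld2, Manf and Hsp90b1, all products of the endoplasmic reticulum and named here after their values were seen, at 2.35-fold, 1.81-fold and 1.21-fold. Camera placed the list upward at an adjusted p of 7.08e-09, and at adjusted p = 0.0238 with an estimated correlation.

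In the hypoxia list, 7 of 12 tested members rose and none fell, also adjusted over the list alone. Adm, encoding the vasodilator adrenomedullin, rose 8.50-fold from 8.58 ± 1.27 to 73.2 ± 2.96 CPM, and the angiogenic factor Vegfa rose 2.17-fold. Camera gave an adjusted p of 2.52e-05, and adjusted p = 0.0293 with an estimated correlation. In the atrophy and autophagy list, 13 of 18 tested members rose and 1 fell, or 14 and 1 adjusted over the list alone (camera adjusted p = 0.000374, and adjusted p = 0.0415 with an estimated correlation). The autophagy receptor Sqstm1 rose 2.05-fold from 518 ± 13.4 to 1063 ± 10.7 CPM, and the muscle ubiquitin ligase Fbxo32 rose 1.71-fold.

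**Figure D3:**
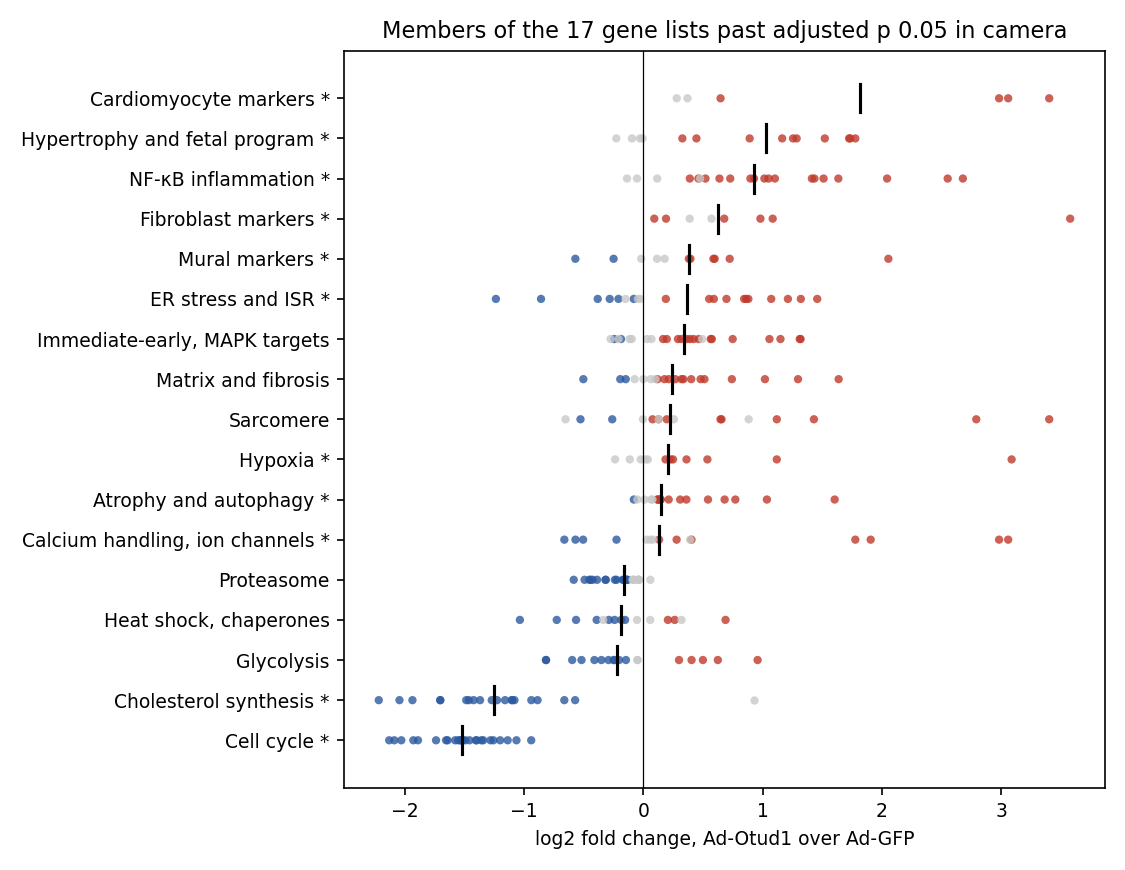
Log2 fold change (Ad-Otud1 over Ad-GFP, horizontal axis) of each tested member of the 17 lists past an adjusted p of 0.05 in camera, with the list median as a vertical bar; red points rose, blue points fell and grey points did not pass the gene-wise test. An asterisk marks the 11 lists that also passed with an estimated correlation, and the cell cycle and cholesterol lists had the lowest medians, -1.52 and -1.25.

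Matrix genes, immediate-early genes, glycolysis, the proteasome and chaperones passed camera with the preset correlation alone. In the matrix and fibrosis list, 13 of 20 tested members rose and 3 fell, also adjusted over the list alone (camera adjusted p = 1.27e-06, and adjusted p = 0.0908 with an estimated correlation). The growth factor Tgfb1 rose 3.11-fold, the matricellular protein Postn rose 2.46-fold, Thbs1 rose 2.03-fold and the collagen Col3a1 rose 1.67-fold from 3302 ± 31.6 to 5525 ± 9.99 CPM. Fibroblast markers were higher in the same libraries. In the immediate-early list, 15 of 24 tested members rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.000906, and adjusted p = 0.191 with an estimated correlation), with Myc at 2.49-fold and the stress-induced factor Atf3 at 2.22-fold higher. In the glycolysis list, 5 of 18 tested members rose and 11 fell, also adjusted over the list alone (camera adjusted p = 0.00382, and adjusted p = 0.191 with an estimated correlation), and Ldha, the lactate dehydrogenase subunit, fell 1.76-fold. In the proteasome list, 16 of 24 tested members fell and none rose, also adjusted over the list alone (camera adjusted p = 0.00140, and adjusted p = 0.0908 with an estimated correlation), and Psmd1 fell 1.50-fold. In the chaperone list, 8 of 15 tested members fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.0101, and adjusted p = 0.0917 with an estimated correlation). The constitutive chaperone Hspa8 fell 2.05-fold and the muscle chaperone Hspb7 rose 1.61-fold.

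The list of ASK1 and MAPK pathway components did not pass camera (adjusted p = 0.370). This list covers transcripts of the components, not the activity of the pathway. Of its 17 tested members, 6 rose and 5 fell, also adjusted over the list alone. The median log2 fold change was -0.03, the mean was 0.14 and the test pointed upward. Its members with the smallest p were the adaptor genes Traf2, which rose 4.49-fold from 9.0 ± 1.6 to 40.5 ± 0.625 CPM, and Traf6, which rose 2.76-fold. Txn1, encoding thioredoxin, an inhibitor of ASK1, fell 1.32-fold from 254 ± 12.1 to 193 ± 4.01 CPM, and the kinase Mapkapk2 rose 1.2-fold.

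Mitochondrially encoded transcripts took 5.41% ± 0.376 of counts in Ad-GFP and 4.54% ± 0.110 in Ad-Otud1 (SD, n = 3). Of the 13 mitochondrial genes tested, 11 fell and 0 rose, with a median log2 fold change of -0.25. The list of nuclear genes for oxidative phosphorylation did not pass camera (adjusted p = 0.222), with 1 of 30 tested members higher and 13 lower, also adjusted over the list alone. Cox6a2, the muscle isoform of a cytochrome oxidase subunit, rose 2.10-fold and Cox5a fell 1.49-fold. The fatty acid oxidation list did not pass (adjusted p = 0.484), with 7 of 26 tested members higher and 8 lower, or 7 and 9 adjusted over the list alone. Its median was -0.04, whereas its mean of 0.02 and the test pointed upward. Acsl1, an acyl-CoA synthetase, rose 2.73-fold and the thiolase Acaa2 fell 2.01-fold. Mitochondrial dynamics and mitophagy genes did not pass (adjusted p = 0.710), with 5 of 17 tested members higher and 4 lower, also adjusted over the list alone, and Pink1 rose 1.34-fold.

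Among the remaining lists, the counts of members adjusted over the list alone are given in brackets and none passed camera. In the interferon list (adjusted p = 0.116), 15 of 26 tested members rose and 3 fell [15 and 3], with Rsad2 higher by 2.93-fold. In the list of p53 targets (adjusted p = 0.351), 6 of 20 rose and 8 fell [7 and 8], and the cyclin-dependent kinase inhibitor Cdkn1a fell 1.49-fold. In the NRF2 list (adjusted p = 0.157), 7 of 20 rose and 7 fell [7 and 7], with haem oxygenase Hmox1 higher by 2.03-fold and Prdx1 lower by 1.38-fold; its median was -0.01, whereas the mean of 0.08 and the test pointed upward. In the cell death list (adjusted p = 0.805), 7 of 21 rose and 5 fell [7 and 5], with Casp12 higher by 2.0-fold and Apaf1 lower by 1.77-fold. Of the OTU deubiquitinases (adjusted p = 0.351), 4 of 13 rose and 3 fell [4 and 3]. Besides Otud1, those that rose included Tnfaip3, an inhibitor of NF-κB signalling, at 2.15-fold, and Otub2 at 1.95-fold. In the list of oxidant-producing enzymes (adjusted p = 0.958), 3 of 7 rose and 3 fell [3 and 3], and the oxidase Nox4 rose 1.39-fold; the median of 0.02 and the test pointed upward and the mean of -0.02 downward. In the ribosomal protein list (adjusted p = 0.889), 5 of 23 rose and 4 fell [5 and 4]. None of the 6 tested renin-angiotensin genes changed [none], and that list had an adjusted p of 0.889.

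Outside the lists, the largest rises among expressed named genes included Adra1a, the alpha-1A adrenergic receptor, at 31.4-fold from 1.05 ± 0.159 to 33 ± 0.89 CPM. The epidermal growth factor receptor Egfr rose 13.5-fold to 31.8 ± 0.0248 CPM, the actin-bundling protein Dmtn rose 15.5-fold to 61.5 ± 2.56 CPM, the cardiac transcription factor Gata5 rose 8.72-fold to 96.5 ± 2.06 CPM, and the adaptor Cass4 rose 9.33-fold to 9.97 ± 0.147 CPM. A gene model on chromosome 3 named Srm, the symbol of spermidine synthase, rose 14.4-fold, with uneven counts of 345, 133 and 514 in the Ad-Otud1 libraries. Whether it shares reads with a near-identical copy was not tested. The signalling ligand Wnt3a held 184 counts summed over Ad-GFP and 1 over Ad-Otud1, a ratio of 174 with a 95% counting interval of 30.9 to 6929, and Wnt5b fell 4.52-fold. Il1rl1, the receptor for interleukin-33, fell 4.73-fold, the chromatin remodelling subunit Ino80b fell 5.85-fold and the major histocompatibility gene RT1-T24-1 fell 4.42-fold, the last with uncertainty because near-identical copies can share its reads. A copy of Coa8 that shares its name with another gene also fell, from counts of 109, 65 and 64 to 1, 0 and 7, so that the size of its fall rests largely on Ad-Otud1 replicate 3, and shared reads add to the uncertainty. Tbcb, a tubulin-folding cofactor, fell 16.2-fold with uneven Ad-GFP counts of 201, 231 and 10, and its call was lost in limma-voom (adjusted p = 0.127).

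**Figure D4:**
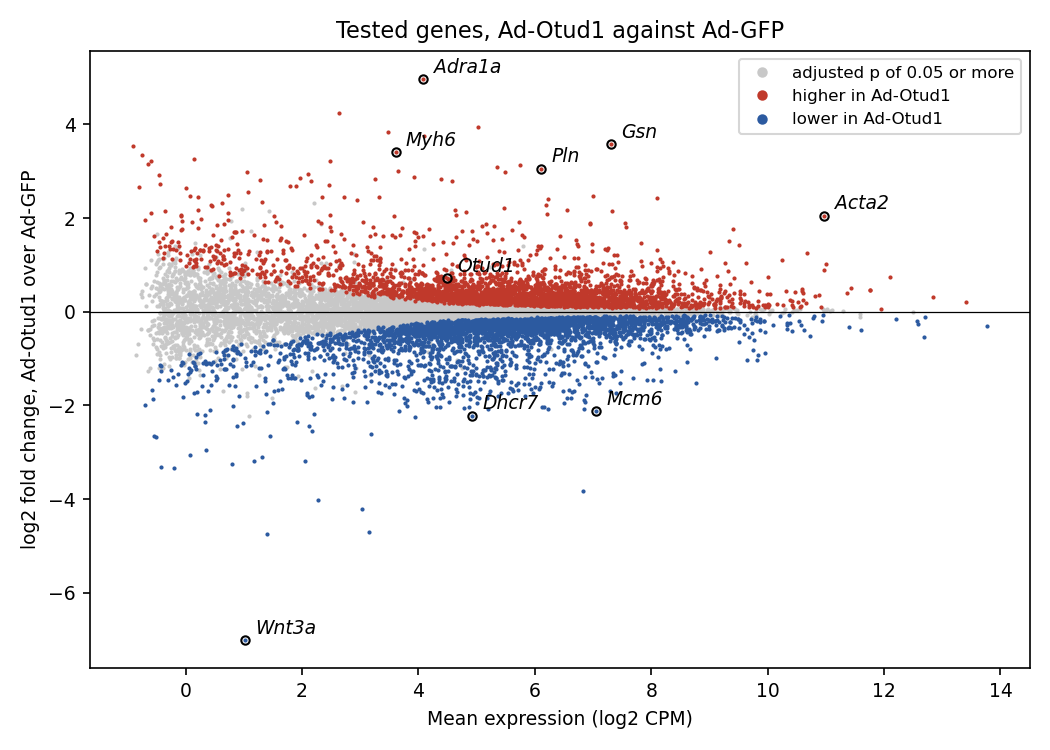
Log2 fold change (Ad-Otud1 over Ad-GFP, vertical axis) against mean expression in log2 CPM (horizontal axis) for the 12552 tested genes, coloured by the edgeR test, with 9 genes named in the text circled. Similar numbers of genes were higher (3045) and lower (3177), and most of them lay close to 0, whereas the fitted value of Wnt3a, with 1 count in Ad-Otud1, depends on the small count that the fit adds.

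Across all genes, 6222 of 12552 tested genes (49.6%) changed at an adjusted p below 0.05 in edgeR, 3045 higher and 3177 lower in Ad-Otud1. Most changes were small, since 4440 of the 6222 (71.4%) were below 1.5-fold and the median absolute log2 fold change was 0.38. At least 2-fold changes were called for 811 genes, 335 higher and 476 lower. Against a minimum change of 1.5-fold, a test chosen after the data were seen, 866 genes passed. The 3 libraries of each group did not overlap for 7150 tested genes (57.0%), against 10% by chance for 3 against 3. The first principal component took 61.5% of the variance and separated the groups. Spearman correlations across genes, which are not independent replicates, were 0.994 to 0.995 within groups and 0.972 to 0.973 between them. Of the 31 lists tested, 17 passed camera, 12 upward and 5 downward, and 11 of them held with an estimated correlation. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. If each group came from a single culture, a difference between cultures could not be told apart from an effect of Otud1.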

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

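The test against 1.5-fold, the robust dispersion and the removal of genes uneven within a group were chosen after the results were seen; the other alternatives were fixed before. The number of changed genes ranged from 5495 (DESeq2) to 6473 (without uneven genes) over every alternative but the test against 1.5-fold and the libraries left out, and from 5494 to 5912 with a library left out, compared with 6222. No gene called both originally and under an alternative changed direction. Genes changed at least 2-fold numbered 811, and ranged from 611 (test against 1.5-fold) to 978 (no filter), with 790 to 822 when a library was left out. Testing against 1.5-fold left 866 genes, 356 higher and 510 lower, because the hypothesis tested is stricter, and Otud1, at a log2 fold change of 0.72, did not pass it (adjusted p = 0.316). The Otud1 change kept its direction and its call elsewhere, between 0.70 and 0.73 under the other scalings, filters and tests and between 0.65 and 0.82 with a library left out. With an estimated correlation 11 lists passed in place of 17. The cause was not tested, but a correlation above the preset 0.01 cannot be the whole cause. For the chaperone list the estimate was -0.0646, yet the adjusted p in camera rose from 0.0101 to 0.0917. For the cell cycle list it was 0.00167, and the adjusted p rose from 6.90e-92 to 0.000690. The other lists that lost the call had estimates above the preset, from 0.0204 to 0.122. Fry, which asks whether a list moves at all, passed 25, and the other alternatives run for lists gave 17 each. With the replicate block, 5954 genes changed, 5878 of them shared with the 6222, and no call of a named gene or list changed. Same-numbered libraries did not deviate together (correlations -0.003, -0.047 and -0.011), so no pairing was detected. Counting noise weakens such correlations over all genes, so a weak pairing is not excluded.

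Of the named genes other than Otud1, 134 were followed, in 2405 comparisons; 2342 kept their side of the threshold, 63 lost the call, 51 of them in the test against 1.5-fold, and 0 reversed. The remaining losses, with their highest adjusted p, were Krt8 (0.0777; DESeq2 and 3 left-out libraries), Upk3b (0.113; 3 left-out libraries), Map3k5 (0.0596; Ad-GFP replicate 2 or Ad-Otud1 replicate 3 left out), Cyba (0.0581; Ad-Otud1 replicate 1 left out) and Tbcb (0.127; limma-voom and robust dispersion). The scalings moved the median of all genes by no more than 0.02 on the log2 scale. Depth limits mainly genes near the floor, such as Actc1 and Ryr2, with 16 and 22 summed counts in Ad-GFP.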

Other observations

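The 5 gene lists in this part, the marker weighing and the Otud1 tests were chosen after the results were seen; the splits of the libraries were planned before. The lists are described by the number of members that moved, without a list test, since they were chosen for what had been seen. All 30 tested genes of DNA replication and repair fell, including the licensing factor Cdc6 at 4.10-fold, the flap endonuclease Fen1 at 3.87-fold and the repair gene Brca1 at 3.63-fold. Of 14 tested genes of fatty acid synthesis, 11 fell and 1 rose. The fatty acid synthase Fasn fell 1.96-fold and the desaturase Scd2 fell 1.90-fold from 1190 ± 26.2 to 626 ± 5.97 CPM, whereas Srebf1, the transcription factor of this pathway, rose 1.2-fold.

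Of 20 tested cytoplasmic aminoacyl-tRNA synthetase genes, 16 rose and 2 fell, with Eprs higher by 2.14-fold at 1662 ± 7.08 CPM and Yars1 by 1.91-fold. Among 17 tested Wnt ligands, receptors and antagonists, 6 rose and 2 fell, with a median log2 fold change of -0.03 and a mean of -0.29. The negative mean rests on Wnt3a, whose fitted log2 fold change of -7.00 comes from 1 count summed over Ad-Otud1. Wnt11 rose 7.36-fold while Wnt3a and Wnt5b fell. Of 18 tested skeletal muscle genes, 12 rose and 1 fell. Myog, the transcription factor of terminal muscle differentiation, rose 2.47-fold and the embryonic myosin Myh3 rose 4.10-fold.

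All 6 libraries carried regulators of skeletal muscle that heart cells are not known to make, beside low levels of heart structural genes. Myog stood at 73.1 ± 1.56 CPM in Ad-GFP and 181 ± 5.78 in Ad-Otud1, Myod1 at 35 ± 2.1 and 32.2 ± 1.13, and Col1a1 and Fn1 were among the 3 most abundant genes. An excess of cardiac fibroblasts over cardiomyocytes would leave Myog and Myod1 at the floor. The lowest value of either in any library was 31.5 CPM, but these levels prompted the question and are no independent test of it. They argue only against such an excess as the whole source of Myog and Myod1. Whether it lowered the heart structural genes is left open. Cells with a skeletal myoblast-like programme are a possible source that the levels neither exclude nor single out: 40.9% of the 22 skeletal muscle genes in the table reached 10 CPM in every library, against 18.2% of the 11 cardiomyocyte, 40% of the 10 fibroblast and 75% of the 12 mural markers, and Myl1, Myh8 and Jph1 stayed near 0. A loss of heart gene reads in counting was not tested, since it needs the reads.

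Cardiomyocyte markers were higher in Ad-Otud1, led by Myh6 and Pln. The 6 tested markers alone do not decide whether these cultures held a larger share of cardiomyocytes: 4 rose and none fell, with the lowest log2 fold change 0.28 ± 0.15 (SE), of Nkx2-5. Added cardiomyocytes would also bring Actc1, Actn2, Mybpc3 and Tnni3, which are abundant in them, but in a comparison settled on after other forms had been tried these together stood at 2.24 ± 0.223 CPM (SE) in Ad-Otud1, below the gains of Tnnt2 (147 CPM), Pln (109), Myh6 (20.2) and, by a small margin, Ryr2 (3.09 ± 0.157). This argues against a larger share as the whole cause, least firmly for Ryr2, and only if the reads of these 4 genes were not lost in counting, which was not tested. A regulated rise of these genes with Otud1, or a change in another cell type that expresses them, remains open.

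Otud1 rose less than 2-fold although it was the gene delivered. The choice among 4 scalings between libraries did not account for this, since the largest log2 fold change over them was 0.73. These scalings differed little, with TMM factors from 0.994 to 1.01, so an error common to all 4 was not tested. A single mislabelled library is unlikely, because the lowest Ad-Otud1 library lay 6.5 CPM above the highest Ad-GFP library. Reads of the delivered gene that were not aligned or not counted, for example from a sequence of another species, cannot be told apart from low delivery, as the 1368 bp counted model was the only Otud1 sequence information used here.

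The 10 possible splits of the 6 libraries into 3 and 3 are too few for a share below 0.05, as 1 split (the real one) is already a share of 0.1. The real split gave 6222 changed genes, against at most 1 in the other splits, 811 genes changed at least 2-fold against at most 1, and 17 lists past camera against at most 9. Every other split mixes libraries of both groups, so the group difference widens the spread within its sets. That alone leaves few gene calls, so these counts are not a rate of false calls. The list counts did not drop as far, with a median of 5 lists in the other splits. Each set of 3 in those splits holds more libraries of 1 group than of the other. Part of the group difference therefore remains between the sets, and the list counts are no such rate either. Within groups, 1056 tested genes differed over 2-fold between libraries, 170 of them among the changed genes, and 122 of the 1056 averaged 5 CPM or more.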
